A study of Mus musculus with 4 samples.

How the data were processed

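The data are RNA immunoprecipitation libraries from testes of 8-week-old C57BL/6 mice, 2 made with an antibody to LARP7 and 2 with IgG. Per the labels' protocols, tissue was lysed in 150 mM NaCl, the lysate was kept for 4 h with antibody on protein A/G beads, and the beads were washed in 500 mM NaCl. Libraries were made with a small RNA kit and selected for RNAs of 15 to 300 nt. Per the submitters' processing notes, cutadapt, Bowtie2 and RSEM were used with the mouse build mm10; their versions and settings are not given in the sources used here. Each deposited file gives, per gene model, the expected count (an estimated count that need not be whole, in which RSEM splits multiply mapping reads between models) and the TPM of the authors, which divides counts by effective length and scales libraries to one total. The deposited files also hold a posterior SD of each estimated count and the model's length and effective length.

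Each library held 50600 gene models. Gene names were those of the files, and 35715 symbols (70.6%) matched a RefSeq gene table of GRCm38.p6, the assembly of mm10, 938 of them through a synonym. Biotypes and coordinates come from that table. RNA families were summed by RefSeq biotype and the model length of a named member, so "U6-length" means every snRNA model of 107 nt, the length of Rnu6, and some of these may not be U6 copies. 1784 gene models share identical counts with another model, since their reads cannot be told apart. Expected counts were rounded to whole numbers. Before that, 13.4% to 18.9% of all 50600 gene models in a library, those at 0 included, were not whole. The share among genes above 0 is thus higher.

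The main test was fixed before the data were examined: edgeR 4.0.16 in R 4.3.3, filterByExpr, TMM factors, robust quasi-likelihood F tests, two-sided, with Benjamini-Hochberg adjustment over 12234 genes and a threshold of 0.05. Antibody was the model's term. TMM factors were 0.558 and 0.673 for the LARP7 libraries and 1.85 and 1.44 for the IgG libraries, so scaling by TMM or by library totals gives different folds for every gene. Standard errors are the unshrunk log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes, and error terms are SDs over 2 libraries. Libraries held 4411271 to 6994514 counts. More counts did not bring a smaller error: the SE was 1.07 for Rn7sk, with 1247782 LARP7 counts, and 0.564 for Snord8, with 673. In a simulation of this comparison over 11501 genes, edgeR called 2 of 47 genes changed 2-fold and 11 of 47 changed 4-fold. It called 36 of 49 changed 8-fold and 36 of 45 changed 16-fold. In the same simulation 20 of 11313 unchanged genes were called, 19% of 105 calls. The data gave far more calls (1772 higher and 1185 lower), some of them under 4-fold, such as Larp7 (log2 fold change -1.46). The adjustment over genes is looser where more genes are called, so the simulated rates need not hold for these data. The simulated false share of 19% was still above the 0.05 that the threshold aims at, in a single run. The share of false calls in the data is not known and may also exceed 0.05.

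Lists of genes were fixed before the data were examined: 7SK, U6, U6 guide snoRNAs, Pol II snRNAs, other Pol III RNAs, box C/D and H/ACA snoRNAs, scaRNAs, microRNAs, snoRNA host genes, histone, ribosomal protein and mitochondrial RNAs, mRNAs of the 7SK complex and U6 partners, and markers of spermatogonia, spermatocytes, round and elongating spermatids, Sertoli, Leydig, and peritubular, vascular and blood cells. Lists with at least 3 tested members (19) were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Camera compares a list with all other genes, and fry's PValue tests whether a list's genes move, on balance, one way. With an estimated correlation 0 of the 19 lists were called by camera, 0 had an unadjusted p under 0.05, and fry called 0, with 6 at an unadjusted p under 0.05. The estimated form rests on the few residual degrees of freedom of 4 libraries, so it could call little. It ended calls of lists with a low estimated correlation (scaRNAs -0.0318, histone mRNAs 0.0826) and a high one (U6 guides 0.542) alike. A call lost there thus does not show that correlation made it. For the lists with the smallest camera p-values the estimates lay well above the preset 0.01. They were 0.256 for microRNAs, 0.337 for box C/D snoRNAs and 0.417 for elongating spermatid markers. Those small p-values therefore rest on the preset. The 7SK and U6 lists had 1 tested member each and no list test; with members at 0 counts in a group set to their bound, no list median changed. On simulated data, 2 of 100 random lists had p under 0.05. The gene Rnu73b, which the fixed Pol II pattern also matched, was left out of that list, a departure from the pattern as written. Of the U6 guides listed, Snord9, Snord10 and Snord94 were not found by symbol and are not analysed here.

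Named genes followed a rule fixed beforehand. It took Rn7sk, the most abundant U6 model, Larp7 and the measured U6 guides, then the 3 most abundant members of each list. It also took the 10 genes with the largest rises and the 10 with the largest falls among those called, with a mean of at least 10 CPM and both LARP7 libraries beyond both IgG libraries. All 1772 and 1185 called genes had groups that do not overlap; chance alone separates 2 libraries from 2 with a probability of 0.333. Placeholder symbols (300 of the 1002 genes meeting the last part for rises, 61 of 602 for falls) were not named. Members named because a list held 5 or fewer calls were chosen after their values were seen. A group at 0 counts was given a floor of 3 counts over the group, and totals of 1 to 3 counts an exact 95% counting interval. Both use TMM-scaled library sizes, and library totals would give smaller rises with the LARP7 antibody.

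Alternatives were RLE factors, library totals, TMM on genes outside the small RNA lists, no filter beyond 1 count, at least 1 CPM in 2 libraries, DESeq2 1.42.0, limma on log2(TPM + 1) for genes with a mean TPM of at least 1, the replicate number as a block, leaving out each library, a minimum log2 fold change of 1, an adjusted p under 0.10, families summed, camera with an estimated correlation, fry, TPM shares, and shares without the 10 genes with the most counts. The sum of U6-length models, the removal of genes that share reads, and the classes by biotype were added after seeing the data. Read lengths were derived from the effective lengths in the deposited files, as the step in effective length between single-length models, to the nearest percent. Plots and random lists used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.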

Results

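RNA bound in complexes with LARP7 was measured in testes of 8-week-old C57BL/6 mice. In RNA immunoprecipitation (RIP), an antibody on beads pulls a protein out of a tissue lysate together with its RNAs, and a non-specific IgG measures the background of RNAs that stick without it. LARP7 is a La-related protein known to bind the 3' end of 7SK RNA and of the spliceosomal U6 RNA. There were 2 groups of 2 libraries, 4 in all: the LARP7 RIP (replicates 1 and 2) and the IgG RIP (replicates 1 and 2). The libraries were made with a small RNA kit and selected for inserts of 15 to 300 nt. Expected counts summed to 6918040 and 6502682 in the LARP7 libraries and to 6994514 and 4411271 in the IgG libraries. Replicates were distinct libraries, with a chi-square per degree of freedom of 162 over 9556 genes for the LARP7 RIP and of 64.5 over 12453 genes for the IgG RIP. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Reads of 61 to 75 nt made up 47% ± 9.90 (SD, n = 2) of the LARP7 libraries and 31% ± 5.66 of the IgG libraries. Across genes, which are not independent replicates, log2 CPM (counts scaled by library size) correlated at r = 0.912 between LARP7 replicates and 0.872 between IgG replicates.

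**Figure D1:**
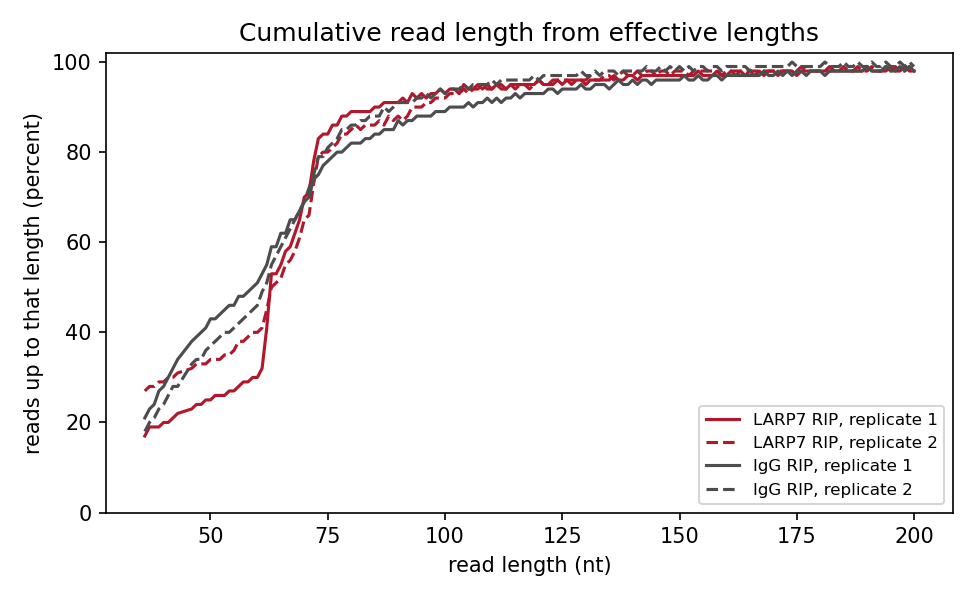
Share of reads (y axis, percent) up to each length (x axis, nt), from the effective lengths in the deposited files, for replicates 1 and 2 of the LARP7 RIP (red) and the IgG RIP (grey). Reads of 61 to 75 nt made up 54% and 40% of the LARP7 libraries and 27% and 35% of the IgG libraries.

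The first question was which kinds of RNA the LARP7 complexes held. Small nucleolar RNAs (snoRNAs), which guide chemical modification of other RNAs, with the related Cajal body scaRNAs, took 33.5% ± 10.1 (SD, n = 2) of the counts in the LARP7 RIP and 14.7% ± 3.60 (SD, n = 2) in the IgG RIP. 7SK, the non-coding RNA that holds the elongation factor P-TEFb inactive, took 9.45% ± 6.89 and 0.976% ± 0.60. Protein-coding genes took 17.7% ± 3.84 of the counts with the LARP7 antibody and 40.3% ± 2.86 with IgG. Mitochondrial RNAs took 0.107% ± 0.0304 and 1.42% ± 0.407, and snRNAs other than those of U6 length took 0.813% ± 0.0760 and 3.89% ± 1.84. Long non-coding RNAs (lncRNAs) took 8.38% ± 3.29 and 4.48% ± 1.06. With TPM in place of counts, the LARP7 minus IgG difference of the lncRNA share was -0.0987 percentage points. The 10 genes with the most counts held 53.2% ± 6.65 of the LARP7 RIP and 48.2% ± 3.86 of the IgG RIP. No test was made on these shares; the smallest exact two-sided permutation p that 2 libraries against 2 can give is 0.333.

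**Figure D2:**
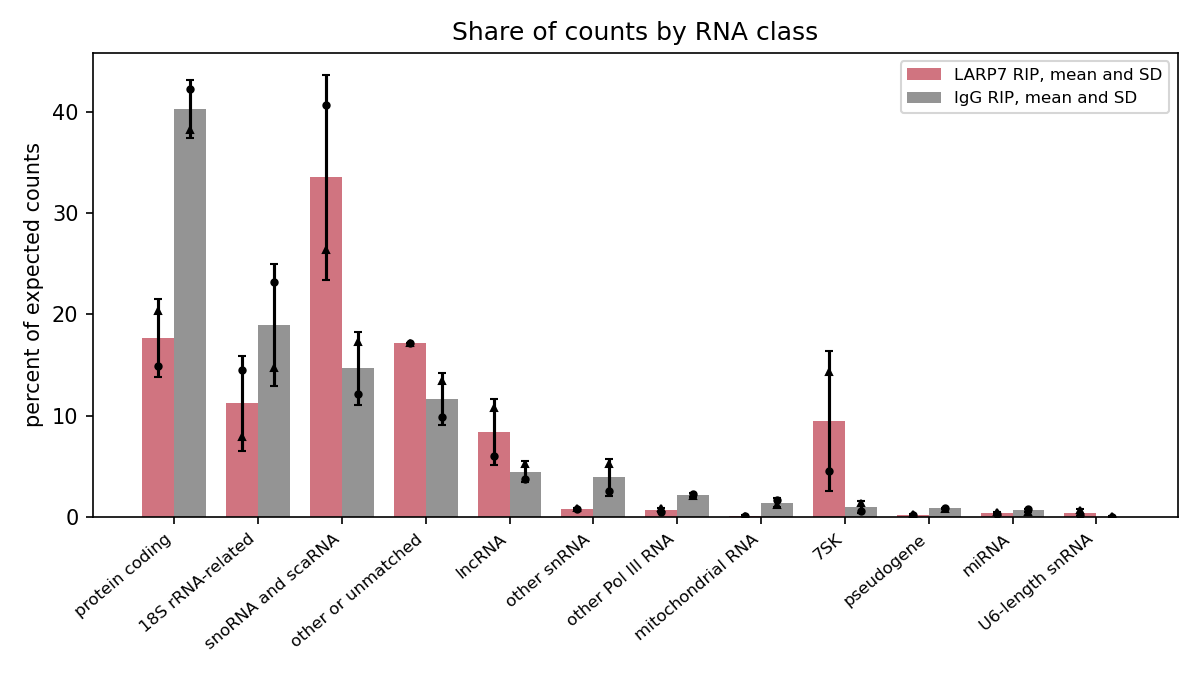
Share of the expected counts (y axis, percent) that each RNA class (x axis) took in the LARP7 RIP (red) and the IgG RIP (grey). Bars are means of 2 libraries, error bars are SD, and circles and triangles are replicates 1 and 2. The snoRNA and scaRNA share was 33.5% with the LARP7 antibody and 14.7% with IgG, and the protein-coding share was 17.7% and 40.3%.

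Among 12234 genes tested, 1772 were higher and 1185 lower with the LARP7 antibody (edgeR quasi-likelihood test, TMM scaling, adjusted p under 0.05). Of the genes higher, 1096 were protein-coding (1044 lower, of 9932 tested), 107 were lncRNAs (28 lower, of 501) and 69 belonged to the snoRNA and scaRNA class (3 lower, of 187). With library totals these classes had 198, 25 and 30 genes higher and 5173, 157 and 17 lower. Among the named genes with the largest rises, Snord107, a box C/D snoRNA, had a mean of 497 ± 166 CPM against 7.46 ± 6.90 (SD, n = 2 each; log2 fold change 6.08, SE 0.92, edgeR adjusted p = 0.00459). Med23, which encodes a Mediator subunit (chromosome 10, 24869986 to 24913529), had 933 ± 728 CPM against 19.5 ± 10.3 (log2 fold change 5.59, SE 0.90, edgeR adjusted p = 0.00510). The transporter gene Slco1a6 had 240 counts with the LARP7 antibody and 5 with IgG (log2 fold change 6.64), but RSEM's posterior SD reached 1.09 times its count in a library, so its share of multiply mapping reads is uncertain. Among the genes with the largest falls, Lpcat2b, Tmco5, Prr30 and Glrx3 had log2 fold changes of -2.85, -2.75, -2.73 and -2.71, with edgeR adjusted p of 0.00619, 0.0106, 0.00434 and 0.00527. Grtp1 had -2.82 (edgeR adjusted p = 0.0224), and was not called without LARP7 replicate 1 (-2.46), LARP7 replicate 2 (-3.33) or IgG replicate 2 (-1.66). The split of calls followed the scaling: 59.9% of calls were higher with TMM and 7.74% with library totals alone (483 higher, 5759 lower), where the median log2 fold change of all genes lay 1.42 below that with TMM. The 1185 genes lower with TMM were all lower with library totals too, and 460 of the 1772 were higher with both. Without LARP7 replicate 2, 660 genes enriched and 197 genes depleted were called. Of these, 381 and 167 were protein-coding. Without IgG replicate 1, 643 protein-coding genes were lower. The snoRNA class held 42 genes higher without LARP7 replicate 1, 28 without LARP7 replicate 2 and 115 without IgG replicate 2. The lncRNA class held 67 and 35 without the LARP7 replicates, against 12 and 4 lower, and 18 lower without IgG replicate 2. DESeq2 called 1433 genes higher and 653 lower.

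The known partners were compared next. 7SK RNA (Rn7sk, ENSMUSG00000065037.1, chromosome 9, 78175302 to 78175633) had a mean of 148000 ± 93000 CPM with the LARP7 antibody against 6395 ± 4780 with IgG (SD, n = 2 each). That was 23.1-fold more (log2 fold change 4.53, SE 1.07, edgeR adjusted p = 0.0167), and 3.27 on the log2 scale with library totals. The call was lost without LARP7 replicate 1 (5.04, adjusted p = 0.0791) or LARP7 replicate 2 (3.68, adjusted p = 0.208), with both values on the same side. Rnu6 (ENSMUSG00000095132.1, chromosome 17, 13432033 to 13432139), the U6 model with the most counts, had 116 ± 95.2 CPM against 0.786 ± 0.00697 (log2 fold change 7.17, SE 0.82, edgeR adjusted p = 0.00223). U6 copies share reads, and the posterior SD reached 5.37 times the Rnu6 count in a library. The sum over all 383 snRNA models of 107 nt, the length of Rnu6, an alternative chosen after seeing the data, was therefore set beside it. These U6-length models together had 6379 ± 4850 CPM against 216 ± 263 (log2 fold change 4.88, SE 1.30, edgeR adjusted p = 0.0241). The value was 3.69 with library totals, and 3.76 (adjusted p = 0.105) without LARP7 replicate 2. The IgG libraries lay apart, at 29.9 and 402 CPM, and the value was 3.97 without IgG replicate 1 and 7.77 without IgG replicate 2. Singly, 36 of the 72 U6-length models tested were higher and 0 lower in edgeR, and with library totals 47 were higher and 0 lower. All 383 models together had 384 and 2550 counts in the IgG libraries, against 11332 and 42501 in the LARP7 libraries. Single models could thus pass the filter on their LARP7 counts alone, which left little room for a fall. Since copies also share reads, these numbers are not separate support for the summed rise.

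No rise was called for the sums of U1-, U2- or U5-length snRNAs, 7SL, Y RNA or 5S rRNA. The U5-length family had 659 ± 288 CPM with the LARP7 antibody and 6797 ± 7190 with IgG (log2 fold change -3.37, SE 1.03, edgeR adjusted p = 0.0347). That call rested on IgG replicate 2, without which the value was -1.34 (adjusted p = 0.192), and it was lost without LARP7 replicate 1 (-3.00, adjusted p = 0.274) or LARP7 replicate 2 (-3.92, adjusted p = 0.208). The U1-length family missed the threshold at -2.44 (SE 0.84, edgeR adjusted p = 0.0531). It passed without IgG replicate 1 (-2.94, adjusted p = 0.00324), with library totals (-3.76), without a filter (-2.52), with DESeq2 (-2.48) and with limma on TPM (-4.99). The U2-length family (log2 fold change -0.06, SE 0.81), 5S rRNA (-0.03, SE 0.80), 7SL of the signal recognition particle (-1.29, SE 0.74) and Y RNA (-1.08, SE 0.95) passed no threshold with TMM. With library totals 7SL and Y RNA were called lower (-2.77 and -2.31), and 7SL also with DESeq2 (-1.32). With limma on TPM the U2-length family, 5S rRNA, 7SL and Y RNA were all called lower (-2.65, -2.67, -3.95 and -3.08). The Y RNA value was 1.39 without IgG replicate 2, and was called without IgG replicate 1 (-1.96, adjusted p = 0.0449). Of 9 Pol II snRNAs tested, 1 was higher and 4 lower, and the same numbers held adjusted over the list alone; with library totals 1 was higher and 7 lower, and the median was -2.44 against -1.20 with TMM. Rnu7, the U7 RNA of histone pre-mRNA processing, was higher (log2 fold change 4.04), and Rnu5g, Rnu1a1, Rnu12 and Rnu1b6 were lower (-3.51, -2.66, -2.34 and -2.11). Rnu1a1 shares identical counts with other U1 models, 7 in all, so its own value is uncertain. Neither Rnu5g nor Rnu1a1 was called without LARP7 replicate 1 (-3.14 and -2.32), LARP7 replicate 2 (-4.06 and -3.13) or IgG replicate 2 (-1.34 and -1.82). As a list the Pol II snRNA genes were not called (camera adjusted p = 0.180). Without IgG replicate 1 they were called (adjusted p = 0.000179), and without IgG replicate 2 their median lay 0.465 above that of all genes. The 62 other Pol III RNAs, mostly 5S rRNA copies that share reads, held 10 higher and 3 lower members in edgeR, 10 and 3 adjusted over the list alone, with a camera adjusted p of 0.941. With library totals 4 were higher and 45 lower, with a median of -1.41.

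**Figure D3:**
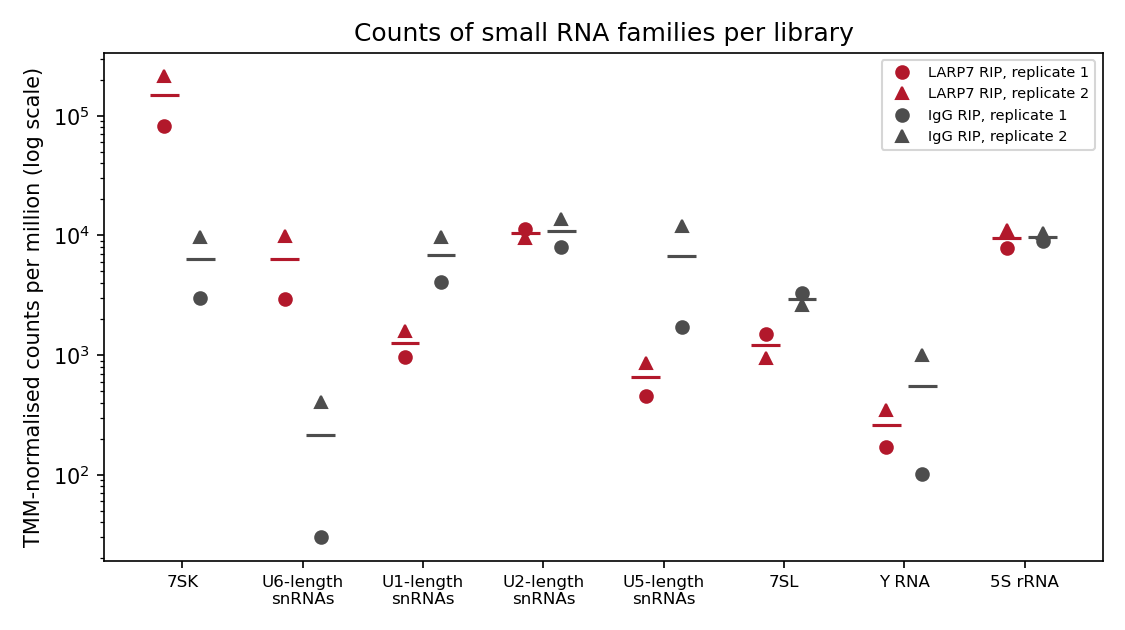
TMM-normalised CPM on a log y axis for 8 small RNA families (x axis), with copies of each family summed. Circles and triangles are replicates 1 and 2 of the LARP7 RIP (red) and the IgG RIP (grey), and lines are group means of 2 libraries. 7SK and the U6-length snRNAs lay higher in both LARP7 libraries than in both IgG libraries (means 148700 against 6375, and 6379 against 216), and U1- and U5-length snRNAs lay lower.

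The U6 guide snoRNAs, which direct methylation of U6, were tested as a list of 3. Snord8 (chromosome 14, 52209786 to 52209884) had 80.8 ± 28.2 CPM against 5.59 ± 2.83 (SD, n = 2 each; log2 fold change 3.87, SE 0.56, edgeR adjusted p = 0.00377), and its value with library totals was 2.54. Snord7 had a log2 fold change of 2.01 (edgeR adjusted p = 0.0462), a call lost with library totals (0.59, adjusted p = 0.540) and without LARP7 replicate 1 (adjusted p = 0.0630), LARP7 replicate 2 (0.469) or IgG replicate 2 (0.0894). Snord67 had 1.41 (adjusted p = 0.12; 2.56 and 0.0147 without IgG replicate 2), with 69.8 ± 31.1 CPM against 26.5 ± 20.2. Thus 2 of 3 were higher, 3 adjusted over the list alone, with a camera adjusted p of 0.0170 for the list, a call lost with an estimated correlation (adjusted p = 0.44) or without IgG replicate 1 (0.0541). Fry gave an unadjusted p of 0.0584, and with library totals 1 was higher and 0 lower. The box C/D snoRNAs had 31 higher and 0 lower members of 81 tested (37 and 0 adjusted over the list alone; camera adjusted p = 2.31e-10; adjusted p = 0.44 with an estimated correlation). The most abundant of them were Snord2 (log2 fold change 3.26, SE 0.98) and Snord49a (3.03, SE 0.90), with edgeR adjusted p of 0.0362 and 0.0334, and Snord83b (2.40, adjusted p = 0.052; 2.73 and 0.0230 without IgG replicate 2). The calls of Snord2 and Snord49a were lost without LARP7 replicate 1 (1.98 and 2.76) or LARP7 replicate 2 (3.92 and 3.25), and that of Snord49a with library totals (1.65, adjusted p = 0.0563). With library totals 13 box C/D snoRNAs were higher and 6 lower, with a list median of 0.37.

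All of the scaRNAs that were called, 7 of 9 tested, were higher (8 adjusted over the list alone), with a median log2 fold change of 2.51 and a camera adjusted p of 0.000231; the adjusted p was 0.44 with an estimated correlation. Scarna2 had 234 ± 67.2 CPM against 43.4 ± 9.17 (SD, n = 2 each; log2 fold change 2.43, SE 0.57, edgeR adjusted p = 0.0160), and missed the threshold narrowly without IgG replicate 1 (2.23, adjusted p = 0.0510). Scarna17 and Scarna10 had log2 fold changes of 2.12 and 2.51. With library totals 2 scaRNAs were higher and 0 lower, the median was 1.01, and Scarna2, Scarna17 and Scarna10 were not called (1.01, 0.75 and 0.92). Scarna17 was not called without LARP7 replicate 1 (2.24), LARP7 replicate 2 (1.97) or IgG replicate 1 (1.90), and Scarna10 not without LARP7 replicate 1 (1.30), LARP7 replicate 2 (3.16) or IgG replicate 2 (1.98). The box H/ACA snoRNAs had 7 higher and 2 lower members of 24 (10 and 2 adjusted over the list alone), and a camera adjusted p of 0.0433; the adjusted p was 0.719 with an estimated correlation. Snora34, Snora3 and Snora61 had log2 fold changes of 1.62, 1.79 and 2.02, all lost without IgG replicate 1 (1.35, 1.66 and 1.45), and Snora61 also without LARP7 replicate 1 (1.30). With library totals they had 0.24, 0.40 and 0.62 and were not called. The list's call was lost without LARP7 replicate 2 (adjusted p = 0.127) or IgG replicate 1 (0.515), and its median was 1.01 with TMM and -0.31 with library totals (2 higher, 4 lower). The members lower were Snora70, with 0 counts in both LARP7 libraries against 14 and 19, and a Snora16a model with 0 against 57 and 69. The other Snora16a model had 18 and 34 against 0 and 2, with a posterior SD of 10.1 times its count, so the split between these copies is uncertain. The snoRNA host genes, which carry snoRNAs in their introns, had 9 higher and 0 lower members of 19 (11 and 0 adjusted over the list alone; camera adjusted p = 0.000195; adjusted p = 0.44 with an estimated correlation). Snhg1 and Gas5 had log2 fold changes of 2.63 and 2.54, lost without LARP7 replicate 1 (2.82 and 2.22), LARP7 replicate 2 (2.38 and 2.78) or IgG replicate 1 (2.13 and 1.84). Rpl7a had 1.85 (adjusted p = 0.065; 2.60 and 0.0236 without IgG replicate 2). With library totals 2 hosts were higher and 2 lower, and Snhg1 and Gas5 were not called (1.31 and 1.21). Whether counts of a host model came from small RNAs within it was not tested.

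MicroRNA gene models, which are annotated precursors and not mature arms, were higher in 69 of 87 cases and lower in 2 (73 and 3 adjusted over the list alone). Their median log2 fold change was 2.95, and 1.53 with library totals (48 higher, 3 lower); camera gave an adjusted p of 3.08e-31, and the adjusted p was 0.44 with an estimated correlation. Mir92-1, of the Mir17-92 cluster (chromosome 14, 115044427 to 115044506), had 148 and 388 counts in the LARP7 libraries and 0 in both IgG libraries. With TMM-scaled library sizes it was at least 416-fold higher, against a floor of 3 counts over the IgG group (edgeR adjusted p = 0.00122). This bound would be lower with library totals. Mir127 had 194 counts with the LARP7 antibody and 3 with IgG, a TMM-scaled ratio of 151 with a 95% counting interval of 50.8 to 737. Its log2 fold change was 7.12 with TMM and 5.72 with library totals. Mir34c, a microRNA abundant in male germ cells, had 32.7 ± 12.8 CPM against 0.472 ± 0.00418 (SD, n = 2 each; log2 fold change 6.07, SE 0.56, edgeR adjusted p = 0.00122). Mir103-2 and Mir30c-2 had log2 fold changes of 5.51 and 5.48, with posterior SDs of up to 0.751 and 0.330 of the count. The 3 models with the most counts went different ways: Mir6240 had -1.69 (adjusted p = 0.0978), Mir6236 -2.25 (adjusted p = 0.0288) and Mir5117 2.40 (adjusted p = 0.0249). In the RefSeq gene table Mir5117 was matched to the locus of the host gene Gas5 (chromosome 1, 161034601 to 161038539). Their values may thus not be independent. Mir6236 lost its call without LARP7 replicate 1 (-2.05), LARP7 replicate 2 (-2.50) or IgG replicate 2 (-1.81), and Mir5117 without LARP7 replicate 2 (2.09) or IgG replicate 1 (2.06) and with library totals (1.06). Mir6516, the other model lower, had 0 counts in both LARP7 libraries against 12 and 13. As a share of all counts the class was 0.364% ± 0.126 with the LARP7 antibody and 0.644% ± 0.164 with IgG. Mir6240 and Mir6236 held most of the class's IgG counts, 53857 and 9888, against 6621 and 980 with the LARP7 antibody. Counting intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

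**Figure D4:**
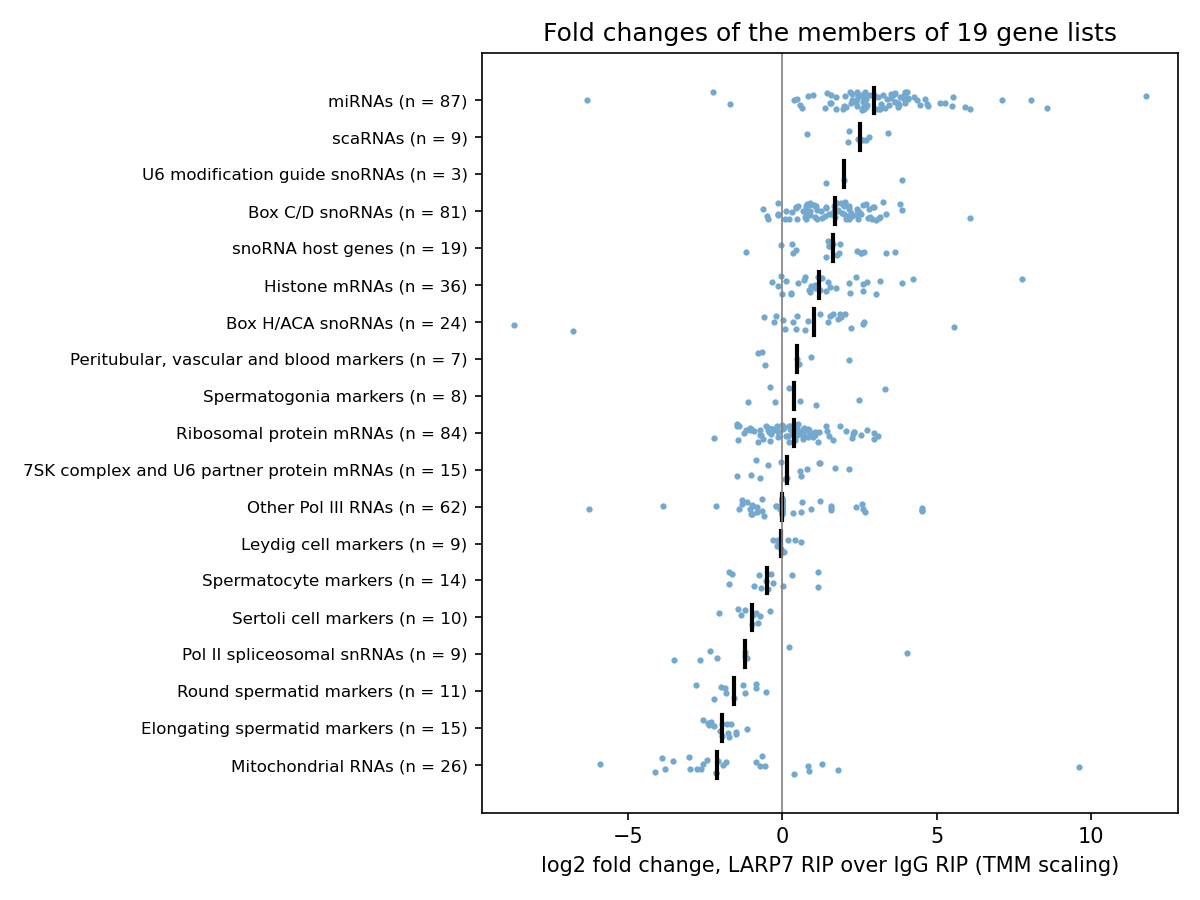
Log2 fold change of LARP7 RIP over IgG RIP with TMM scaling (x axis) for the tested members of 19 gene lists (y axis, with the number tested). Each point is a gene, points are spread vertically at random within a list, and black bars are list medians, from 2.95 for microRNAs to -2.13 for mitochondrial RNAs. Elongating spermatid markers all lay below 0.

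Messenger RNAs went both ways. The histone mRNAs had 11 higher and 0 lower members of 36 (12 and 0 adjusted over the list alone; camera adjusted p = 9.12e-05; adjusted p = 0.44 with an estimated correlation), with a median of 1.18 that became -0.16 with library totals (5 higher, 3 lower). Hist1h1a had 44.9 ± 4.11 CPM against 6.54 ± 4.56 (SD, n = 2 each; log2 fold change 2.74, SE 0.52, edgeR adjusted p = 0.00863), while Hist1h4n (1.16, adjusted p = 0.112; 2.05 and 0.0367 without IgG replicate 2) and the testis-specific Hist1h2ba (0.70, adjusted p = 0.264) were not called. Ribosomal protein mRNAs held 12 higher and 3 lower members of 84 (9 and 2 adjusted over the list alone) and were not called as a list (camera adjusted p = 0.154). Their median was 0.37 with TMM and -1.08 with library totals, where 3 were higher and 32 lower. Rpl13 stood apart with 72230 ± 12600 CPM against 10910 ± 5170 (log2 fold change 2.73, SE 0.87, edgeR adjusted p = 0.0433), a call lost without LARP7 replicate 1 (2.88, adjusted p = 0.233) or LARP7 replicate 2 (2.54, adjusted p = 0.388), and with library totals (1.39, adjusted p = 0.106). Whether counts of Rpl13 or other protein-coding models came from small RNAs within them was not tested, so they need not be mRNA. Rpl5 and Rpl4 had 0.70 and 0.86 (adjusted p = 0.449 and 0.441), and the lower members were Rps7, Rps24 and Rpl39l (-2.23, -1.47 and -1.47). Of the 15 mRNAs for proteins of the 7SK complex and of U6 maturation, 2 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.759; list median 0.14, and -1.28 with library totals, 0 higher and 5 lower). Mettl16, whose product methylates U6, had 2.14 (SE 0.47, edgeR adjusted p = 0.0130; 1.74 and 0.0888 without IgG replicate 1; 0.78 and 0.183 with library totals), and Ccnt2 had 1.71. Ccnt1 had 1.19 (adjusted p = 0.0574; 0.0385 without LARP7 replicate 1), and -0.17 with library totals. The Larp7 mRNA itself (chromosome 3, 127536714 to 127553349) had 11.8 ± 3.96 CPM against 32.3 ± 4.77 (log2 fold change -1.46, SE 0.41, edgeR adjusted p = 0.0291). It was not called without LARP7 replicate 2 (-1.15, adjusted p = 0.153), IgG replicate 1 (-1.30, 0.116) or IgG replicate 2 (-1.55, 0.0526).

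Lists of late germ cell and mitochondrial transcripts were called lower by camera, and none of them with an estimated correlation. The elongating spermatid markers, mRNAs of sperm chromatin and tail proteins, had 9 lower and 0 higher members of 15 (15 and 0 adjusted over the list alone), with a median log2 fold change of -1.97 (camera adjusted p = 2.48e-07; adjusted p = 0.44 with an estimated correlation). The most abundant of them missed the threshold over all genes: Prm2 had -1.49 (adjusted p = 0.0993), Odf2 -1.68 (0.0636) and Tnp1 -1.74 (0.0535; 0.0389 without LARP7 replicate 1). At an unadjusted p under 0.05, 15 were lower and 0 higher in edgeR, and DESeq2 called 12 lower and 0 higher. With library totals all 15 were lower, with a median of -3.40. Round spermatid markers had 4 lower and 0 higher members of 11 (5 and 0 adjusted over the list alone; camera adjusted p = 0.000274; adjusted p = 0.44 with an estimated correlation). The testis kinase genes Tssk1 and Tssk2 had log2 fold changes of -2.20 and -2.79 (SE 0.43 and 0.52, edgeR adjusted p = 0.00917 and 0.00794), and Acrv1 had -0.85 (adjusted p = 0.149); with library totals all 11 markers were lower, with a median of -3.02. The mitochondrial RNAs had 13 lower members and 1 higher of 26 (14 and 1 adjusted over the list alone), with a median of -2.13 (camera adjusted p = 0.000261; adjusted p = 0.44 with an estimated correlation). With library totals 20 were lower and 1 higher, with a median of -3.61. mt-Nd4 had 5.64 ± 0.840 CPM against 45.5 ± 1.90 (SD, n = 2 each; log2 fold change -3.01, SE 0.42, edgeR adjusted p = 0.00325). mt-Co2 (-5.91) and mt-Nd6 (-3.80) were also lower, the first with a posterior SD far above its count in a LARP7 library, and the second not called without LARP7 replicate 2 (-3.30). The ribosomal RNAs mt-Rnr2 and mt-Rnr1 (-2.46 and -2.16) and mt-Co1 (-1.91) were not called without LARP7 replicate 1 (-2.94, -2.72 and -2.42) or LARP7 replicate 2 (-2.11, -1.76 and -1.55), and mt-Co1 also not without IgG replicate 1 (-1.87). The exception was the tRNA gene mt-Ty, with 430 counts against 1, a TMM-scaled ratio of 1000 with a 95% counting interval of 179 to 39700. Its log2 fold change was 9.59 with TMM and 8.21 with library totals.

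Of the other cell type markers, those of spermatocytes had 2 lower members of 14, Spag6 and Pgk2 (-1.73 and -1.65), 2 adjusted over the list alone, and a camera adjusted p of 0.197; with library totals 11 were lower, with a median of -2.04. Ldhc had -0.94, Piwil2 1.14 and Piwil1 0.02 (adjusted p = 0.288, 0.0907 and 0.974), and with library totals Piwil2 had -0.26 and Piwil1 -1.39. Spermatogonia markers had 2 higher members of 8, Zbtb16 and Sall4 (2.49 and 3.31), 2 adjusted over the list alone (camera adjusted p = 0.55; list median 0.39, and -1.03 with library totals, 0 higher and 3 lower). Zbtb16 was not called without LARP7 replicate 2 (2.16) or with library totals (1.08). Ddx4 and Dazl, not called, had -1.10 and -0.26. The Sertoli cell markers had 1 lower member of 10, Wt1 (-2.05), and 0 adjusted over the list alone, while with library totals all 10 were lower (median -2.46). As a list they had a camera adjusted p of 0.0354 (adjusted p = 0.44 with an estimated correlation; 0.114 without LARP7 replicate 2), with Clu at -0.78, Ctsl at -0.72 and Amhr2 at -0.41. Of 9 Leydig cell markers, 0 were called by edgeR, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 by DESeq2. Their median was -0.04, their mean 0.05 and the camera direction down (adjusted p = 0.941). Their values were 0.59 for Aldh1a1, -0.14 for Insl3 and -0.30 for Cyp17a1, and with library totals Aldh1a1 had -0.88 and 5 markers were lower. Peritubular, vascular and blood markers had 1 higher member of 7, the macrophage gene Lyz2 (2.15), and 0 adjusted over the list alone (camera adjusted p = 0.835; list median 0.46, and -0.92 with library totals, 0 higher and 3 lower). Lyz2 was not called without LARP7 replicate 1 (2.02), LARP7 replicate 2 (2.29) or IgG replicate 2 (1.99), or with library totals (0.71). Myh11 and Acta2 had 0.93 and -0.65, and Myh11 -0.57 with library totals.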

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

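The tests of transcript length, library scaling, a few abundant RNAs, the share of short reads and few IgG counts were chosen after the results were seen; those of expression level and mRNA length were set before their own results were seen. The mRNA length test was added once the expression-level result was known. The patterns were also narrowed after a first look: round spermatid markers and the U1-length family (edgeR adjusted p = 0.0531) were dropped from them. A first form of the short-read test set the lowest LARP7 share of reads up to 36 nt (17%) against the highest IgG share (21%), rested on 1 library and was replaced, and a second form took all 87 models. First forms of the length and scaling tests set the U6-length against the U5-length family, a pair chosen for its opposite changes, and were replaced; a test of split copies repeated the summed rise and was dropped. A first low-count test took models with a mean of at least 10 CPM over both groups, which the LARP7 counts can reach alone, and was replaced by IgG counts, seen at minimums of 10, 20 and 50 before the last was taken.

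The read lengths come from a column outside the main comparison. Reads of 61 to 75 nt made up 54% and 40% of the LARP7 libraries and 27% and 35% of the IgG libraries, so both LARP7 libraries lay above both IgG libraries. Reads of up to 36 nt made up 17% and 27% against 21% and 18%, and mean read lengths were 65.8 and 63.8 nt against 64.2 and 61.8 nt; both overlapped between the groups.

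7SK and the U6-length snRNAs were higher with the LARP7 antibody and U5-length snRNAs lower, with copies summed. Transcript length or size selection would shift models of like length alike. Against the median of other models within 10% of its length 7SK had 4.36 (SE 1.20) and the U5-length family -4.10 (SE 1.05). The U6-length family had 2.74 (SE 1.37), at about 2 SE. Other models of its length rose by a median of 2.15, against 0.19 for models of the length of 7SK. Length is thus not excluded as a part of the U6-length rise. Scaling between libraries cannot move a ratio within a library, and against each of 5 families outside the pattern the lowest LARP7 ratio was at least 10.2 times the highest IgG ratio for 7SK and 8.86 times for U6-length snRNAs. For the U5-length family scaling stays open, since the lowest IgG ratio to 7SL was 0.559 times the highest LARP7 ratio, and its value was -1.34 (adjusted p = 0.192) without IgG replicate 2. Background carried alike in both groups would leave these ratios alike, so the gaps of 10.2 and 8.86 times argue against it for 7SK and the U6-length snRNAs. Binding of LARP7 complexes is possible for both, but background particular to the LARP7 antibody or its beads was not separated from it.

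Elongating spermatid mRNAs were lower as a list with the LARP7 antibody, with 9 of 15 called. A few RNAs taking most of the counts would lower all mRNAs alike. The list's median lay below that of other protein-coding genes by a log2 difference of -1.72 (SE over its genes 0.10). The list was taken up because camera called it against all other genes, so this test largely repeats that call and is not separate support. Its SE treats the genes as independent, while their estimated correlation was 0.417. The expression level of the mRNAs and the length of the mRNAs were tested with random protein-coding lists: 0 of the 10000 lists matched on mean CPM, and 0 of those matched on model length, had a median as low (percentile 0 in both). What stays open is a difference between the antibodies or beads in the mRNA they carry over, which may lower these mRNAs in 1 group and which the design cannot separate from LARP7 binding. With an estimated correlation the list was not called (adjusted p = 0.44).

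Of 87 microRNA gene models, 69 were higher and 2 lower with the LARP7 antibody. The list was not called with an estimated correlation (adjusted p = 0.44), a form of camera that could call little. The class took a smaller share of the counts (0.364% against 0.644%). Mir6240 and Mir6236 held most of its IgG counts (53857 and 9888, against 6621 and 980 with the LARP7 antibody). That share thus says little about the other models. A larger share of reads up to 36 nt allows at most 0.72 on the log2 scale with library totals, and stays open, since the median of the 36 models with at least 50 IgG counts exceeded that by only 0.36 (SE over genes 0.24). Few counts in the IgG libraries could not account for these 36 models, whose median lay 2.48 (SE over genes 0.24) above that of all genes (2.69 and 2.62 with at least 10 and 20). The other 51 models, at 3.56 (SE over genes 0.34), stay open, since few IgG counts leave them to be tested on their LARP7 counts. A larger share of reads near the length of mature microRNAs also stays open, as lengths below 36 nt cannot be resolved here, and an effect of the LARP7 antibody is possible but was not separated from it.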

How the results depend on the processing

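Alternatives were fixed before the data were examined, except the sum of U6-length models, the removal of genes that share reads and the classes by biotype. The cause of each change was not tested unless stated. The U6 family by symbol kept its call in all alternatives (log2 fold change 3.79 to 7.82). It rests on Rnu6, whose posterior SD reached 5.37 times its count in a library. The sum over all 107-nt models was 4.88 (leave-one-out range of the U6-length family 3.76 to 7.77), and this sum lost its call without LARP7 replicate 2. The 7SK family (Rn7sk) kept its side throughout (1.97 to 5.66) and lost its call only without either LARP7 library (leave-one-out range 3.68 to 5.66). The genes enriched numbered 660 to 2138 and the genes depleted 197 to 922 when a library was left out; the group then has 1 library, assumed to vary like the other group. The genes enriched were 483 with library totals and 82 with limma on log2(TPM + 1), of 1972 genes; the genes depleted were 5759, 551, 653 with DESeq2 and 1921 at an adjusted p under 0.10. No gene called with TMM was called on the other side, except 1 under limma. Library totals and TPM carry no composition factor, and with library totals folds lack the TMM factors, which by construction lowers them. The 10 genes with the most counts held overlapping shares, 57.9% and 48.5% of the LARP7 libraries against 50.9% and 45.5% with IgG. Limma on TPM also changed the test, the filter and the scaling by length. Replicate numbers are shared but the labels do not say that they pair libraries; deviations of same-numbered libraries correlated at 0.2. With the replicate block 2088 genes were higher and 1405 lower, of which 1734 and 1111 were also called without it. The block also gave a call to the U1-length family (-2.35), the Pol II snRNA list (-0.98) and 11 named genes (Ccnt1, Ddx4, Tnp1, Odf2, Piwil2, Prm2, Rpl7a, Hist1h4n, Snord67, Snord83b and Mir6240), ended that of Snord7 (1.97) and turned the Leydig value (-0.068).

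List values are the median minus that of all genes. With an estimated correlation, and with fry, 0 of the 19 lists were called (0 and 6 at an unadjusted p under 0.05). The 11 lists that lost their call so were the U6 guide snoRNAs 2.06, box C/D 1.75, box H/ACA 1.06, scaRNAs 2.55, microRNA models 3.0, host genes 1.69, histone mRNAs 1.23, mitochondrial -2.08, round spermatid -1.53, elongating spermatid -1.92 and Sertoli -0.93. With limma on TPM, U6 guides (0.90), box C/D (0.65), box H/ACA (0.37), scaRNAs (1.14), host genes (0.65) and histone mRNAs (0.32) lost their call, Pol II snRNAs gained it (-1.97) and other Pol III RNAs turned (-1.36). DESeq2 ended the calls of box H/ACA (1.39) and Sertoli (-0.98), and turned other Pol III (-0.079), spermatogonia (-0.075), Leydig (-0.089) and peritubular (-0.59) values, none of them called. With at least 1 CPM in 2 libraries, box H/ACA was not called (0.82), and other Pol III (-0.028) and Leydig (-0.049) turned. Without a filter Pol II snRNAs were called (-1.23), and other Pol III (-0.06), Leydig (-0.028) and peritubular (-0.14) turned. Leave-one-out ranges were 1.59 to 2.60 for U6 guides, -2.22 to 0.46 for the Pol II snRNA list, -0.20 to 0.36 for other Pol III, 0.49 to 2.05 for box H/ACA, -0.74 to 0.16 for spermatocyte, -1.23 to -0.47 for Sertoli and -0.46 to 0.36 for peritubular markers. Library totals changed no list call. They shift all genes nearly alike, and camera compares a list with all other genes, so this could hardly come out otherwise. They ended the calls of 15 named genes: Snord7 (0.59), Snord49a (1.65), Snora34 (0.24), Snora3 (0.40), Snora61 (0.62), Scarna10 (0.92), Scarna17 (0.75), Scarna2 (1.01), Mir5117 (1.06), Snhg1 (1.31), Gas5 (1.21), Rpl13 (1.39), Mettl16 (0.78), Zbtb16 (1.08) and Lyz2 (0.71). Limma on TPM ended those of Rpl13 (0.16), Larp7 (-1.47), Prr30 (-1.62), Hist1h1a (0.071), Gas5 (0.16), Snord49a (0.63), Snord2 (0.54), Snord8 (1.24) and Snhg1 (0.13), and DESeq2 those of mt-Co2 (-5.96), Snord7 (2.03) and Lyz2 (2.16). Calls also ended with RLE factors for Rpl13 (2.78), mt-Rnr1 (-2.11) and Scarna10 (2.56), with TMM outside the small RNA lists for Scarna10 (2.53), with at least 1 CPM for Rpl13 (2.70), Snord7 (1.98), Lyz2 (2.13) and Scarna10 (2.48), and without a filter for Snord7 (1.92) and Lyz2 (2.07). Calls were gained, all lower, with library totals by Cyp17a1, Dazl, Ctsl, Ddx4, Clu, Amhr2, Tnp1, Odf2, Ldhc, Acrv1, Acta2, Prm2, Insl3, n-R5s142, Mir6240, Rn7s1 and Rn7s2, and with limma by Clu, Tnp1, Odf2, Ldhc, Prm2, n-R5s142, Mir6240, Rn7s1 and Rn7s2. DESeq2 gave calls to Tnp1, Odf2, Prm2, Rpl7a, Snord83b, Mir6240, Rn7s1 and Rn7s2, and no filter to Tnp1, Odf2, Rpl7a and Snord83b.

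Among genes and families not called, library totals turned Ccnt1 (-0.17), Myh11 (-0.57), Piwil1 (-1.39), Rpl4 (-0.41), Piwil2 (-0.26), Hist1h2ba (-0.64), Aldh1a1 (-0.88), Rpl5 (-0.73), Rnu2-10 (-1.17) and Hist1h4n (-0.17). Limma on TPM turned Piwil1 (-1.12), Rpl4 (-1.59), Hist1h2ba (-1.45), Rpl5 (-1.91), Rpl7a (-1.12), Rnu2-10 (-2.37), Hist1h4n (-1.04), Snord67 (-0.996) and Snord83b (-0.25). It also turned Snora61 (-0.51), Snora3 (-0.78), Mir5117 (-0.12), Snora34 (-0.92), Snord7 (-0.39), Scarna2 (-0.21), Scarna17 (-0.39) and Scarna10 (-0.20), which were called with TMM. Piwil1 turned with DESeq2 (-0.006), without a filter (-0.055) and with at least 1 CPM (-0.002). RLE factors turned the 5S family (0.028) and n-R5s142 (0.035). Leave-one-out ranges were -0.42 to 0.024 for Dazl, -0.076 to 0.13 for Piwil1, -0.076 to 0.65 for Rnu2-10, -0.43 to 0.25 for Insl3, -0.31 to 0.20 for n-R5s142, -0.40 to 0.43 for the U2-length family, -1.96 to 1.39 for Y RNA and -0.32 to 0.19 for 5S rRNA. Differences of class shares (percentage points, LARP7 minus IgG) moved with TPM for 7SK (1.07), protein-coding (-1.13), microRNA (-0.573) and mitochondrial RNA (-0.311), and turned for lncRNA (-0.0987). Without the 10 genes with the most counts they were 0.771 for U6-length snRNAs, -15.7 for protein-coding, -5.65 for the other snRNA class, -0.492 for microRNA and -2.53 for mitochondrial RNA. The snoRNA and scaRNA difference was then 10.7, against 18.8 with all genes, and the lncRNA difference 7.08, against 3.90. In the simulation 2-fold changes were rarely called, but it made 105 calls, far fewer than the data, where some changes under 4-fold were called.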

Other observations

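The counts by biotype were chosen after the results were seen. Beyond the lists, lncRNA models were called higher more often than lower with TMM, and lower more often with library totals. Reads of any small RNAs within these models were not told apart from reads of the lncRNAs. Of 501 lncRNAs tested, 107 were higher and 28 lower with the LARP7 antibody (21.4% and 5.59%), against 11% and 10.5% of 9932 protein-coding genes, and with library totals 25 were higher and 157 lower. Without LARP7 replicate 1, 67 were higher, and without LARP7 replicate 2, 35. The 10 most abundant lncRNA models, chosen after their values were seen, had log2 fold changes of 2.14 to 3.17, and of 0.81 to 1.82 with library totals, and 7 of them were called by edgeR. Of these, 1700042G15Rik had 7281 CPM against 812 (log2 fold change 3.17, edgeR adjusted p = 0.0194) and 1700029M20Rik had 9310 against 1591 (2.55, adjusted p = 0.0391). With library totals 1700042G15Rik was still called (1.82, adjusted p = 0.0208) and 1700029M20Rik was not (1.22, adjusted p = 0.130).

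A few protein-coding models held large parts of the IgG libraries. Tmem38b took 14.1% ± 2.24 (SD, n = 2) of the IgG counts and 2.08% ± 0.756 of the LARP7 counts, and Lars2 took 5.09% ± 2.62 and 0.776% ± 0.632. Gm42418, which a synonym matches to an 18S rRNA-related gene, took 19% ± 6.05 and 11.2% ± 4.73. None of the 3 was called with TMM (log2 fold changes -1.42, -1.17 and 0.72; edgeR adjusted p = 0.229, 0.357 and 0.566). With library totals Tmem38b and Lars2 were called lower (-2.77 and -2.72). Removing the 10 genes with the most counts left the protein-coding share lower with the LARP7 antibody, by 15.7 percentage points.

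Lists set against random protein-coding lists of the same size and mean CPM gave percentiles of 0.13 for round spermatid, 3.22 for Sertoli cell, 27.6 for spermatocyte, 60.7 for Leydig cell, 85.2 for spermatogonia and 88.4 for peritubular, vascular and blood markers. Histone mRNAs lay at percentile 100 and ribosomal protein mRNAs at 98.9, over 10000 lists each. Random lists do not carry the correlation between members of a list, so these percentiles can be too extreme. Ribosomal protein mRNAs were not called as a list by camera (adjusted p = 0.154).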
